A study of Danio rerio with 12 samples.

How the data were processed

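Whole eyes of wild-type adult male zebrafish were collected 4, 12 and 21 days after crush of the left optic nerve or a sham operation on the right eye of the same fish, per the labels' protocols. Per the same protocols, 5 eyes were pooled per sample, fish were kept at 28 degrees with 14 h of light and 10 h of dark, anaesthesia was 0.033% MS222, and 8 ug of RNA from Trizol and a Qiagen clean-up were made into biotin-labelled cRNA for the Affymetrix zebrafish array. The labels also name eyes collected 6 h and 1 day after the operation, which were not analysed here. The deposited values are signal intensities, 1 per probe set and array, made by the authors with MAS5 and scaled to one trimmed mean per array, per the submitters' processing notes; the version is not given. The table held 15617 probe sets on 12 arrays, with values from 0.1703 to 62980, a mean of 500.1 on each array after trimming 2% at each end, and median signals between 200.3 and 239.6. The raw image files were not used here.

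The groups were the 3 days by 2 treatments, with 2 pools in each of the 6 groups, and the unit of replication was the pool. P-values measure the spread between pools, and the number of arrays, rather than the depth of each array, limits the precision. The comparisons, tests, alternative settings and 27 gene lists were written down before the data were examined. The comparisons were ONX against SHAM at each day, their average over the 3 days, an F-test of whether the ONX effect differs between days, and an F-test between the days in SHAM eyes.

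The 115 Affymetrix control probe sets were set aside. Of the other 15502, 10795 carried 1 gene symbol, 135 several and 4572 none; 1 symbol was updated, and 10711 of those with 1 symbol were found in the RefSeq gene table. After adding 16 to each signal and taking log2, the upper 60% of probe sets by their mean over the 12 arrays was kept, without regard to group. This left 9301 tested probe sets, with a mean signal of at least 135 at the limit, of which 6984 had 1 symbol. Values were not normalized further in the main analysis. The limma package (3.58.1, in R 4.3.3) fitted 1 mean per group, with variances moderated along a trend with signal (6 residual and 4.23 prior degrees of freedom), and p-values were adjusted by Benjamini and Hochberg within each comparison at 0.05. Standard errors are the moderated ones of that fit.

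Genes were named by a rule set beforehand. At each comparison with calls these were the 12 largest rises and the 12 largest falls with 1 symbol and both ONX pools outside both SHAM pools. In a direction without calls they were the 5 probe sets with the smallest p, and for the F-tests the 10 with the smallest p. Called members of the gene lists, or the 4 with the smallest p where none was called, and a fixed set of nerve injury genes were added. Of that fixed set, tuba1a, tuba1c, rho, rbpms2a and isl2b were not found on the array under that symbol.

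Gene lists were tested on 5967 gene symbols, 1 probe set per gene, with camera from limma at its preset correlation between genes of 0.01, adjusted over all 108 tests of 27 lists and 4 comparisons. The same tests were made with the correlation estimated from the data, and with fry. List counts of single genes are given both adjusted over all tested probe sets and adjusted over the list alone, and 15 genes are in more than 1 list. The oocyte, germ cell and testis lists were written after the values were seen and were not tested with camera.

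Same-numbered pools were not treated as pairs in the tests of the main analysis. The values given per pool at days 12 and 21, and their correlations, subtract the SHAM library of the same number. Per the labels the sham eye is the right eye of the same fish, but they do not say how the pools were numbered.

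The analysis was tested on simulated data with the residual spread of each probe set. At day 4 it recovered 22 of 67 probe sets (32.8%) changed 2-fold, 55 of 67 (82.1%) changed 4-fold and 63 of 66 (95.5%) changed 8-fold, with 6 false among 146 calls. Far fewer probe sets were changed in the simulation than were called at day 4, so that the recovery in the data may differ. The list test called 20 of 20 sets of 20 genes with every gene shifted 2-fold, also with an estimated correlation. It called 0 of 20 sets that were not shifted. Smaller shifts, such as those of many lists below, were not simulated. The simulated noise was independent between probe sets. These sets therefore cannot show how the list test behaves where genes are correlated.

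Alternatives tried were an offset of 0 (with a floor of 1) or 64, no filter or the upper 40%, quantile normalization or centring on array medians, no trend or robust moderation, array weights, the pool number within a day as a block, each array left out, only the arrays of one day, an adjusted p of 0.1, an unadjusted p under 0.01 with a 2-fold change, and the mean of a gene's probe sets in the list test. Added after the data were seen were fits without the day 12 pool 1 arrays, without the 4 pool 1 arrays of days 12 and 21, and without these and ONX day 4 pool 1, a block with crossed numbers at day 12, and arrays scaled to the 9 hybridisation or the 24 poly-A spiked controls. The 9 hybridisation controls were the BioB, BioC, BioDn and CreX probe sets. A second series of probe sets for the same controls, marked r2, was left out, while the 24 poly-A controls include their r2 series. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.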

Results

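Gene expression was measured in whole eyes of wild-type adult male zebrafish after crush of the left optic nerve (ONX). The right eye of the same fish, which was lifted from its socket and put back with its nerve intact, was the sham control (SHAM). Eyes were collected 4, 12 and 21 days after the operation and pooled by 5, and RNA from each pool was hybridised to 1 Affymetrix zebrafish array. Each of the 6 groups held 2 pools, which gave 12 arrays in all, so that the number of arrays limits the precision of every value. The question the labels give is how expression in the eye changes over time after the crush. Values are log2 of the deposited signal plus an offset, differences are ONX minus SHAM, and errors are standard errors of the fit with 2 pools per group unless stated otherwise. The unit of replication was the pool of eyes, which the labels name as a biological replicate.

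The arrays were scaled alike, with a trimmed mean signal of 500.1 on each. Spearman correlations between arrays, across 9301 tested probe sets, lay between 0.851 and 0.973 for the 11 arrays other than ONX day 4 pool 1, and between 0.717 and 0.810 for that array against the others. In ONX day 4 pool 1, 27 oocyte genes had a median log2 signal of 12.0, against 5.00 to 5.84 on the other arrays. The list holds egg coat genes such as zp2.6 (14.5 against at most 7.63 elsewhere) and zp3.1 (13.8 against at most 7.56). A list of 12 germ cell genes of either sex had a median of 9.15 on that array and 4.83 to 5.48 on the others, and 26 testis genes had 5.98 and 5.24 to 5.86. These 3 lists and genes were chosen after the values were seen. Because of this array, list values for day 4 are also given for each ONX pool.

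**Figure D1:**
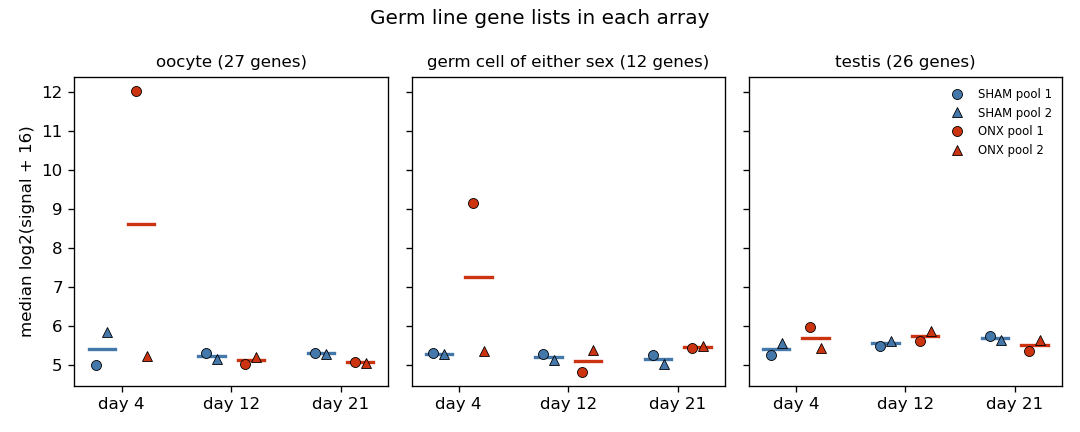
Median log2(signal + 16) of the oocyte list (27 genes), the germ cell list (12 genes) and the testis list (26 genes), 1 point per array, with the 12 arrays by day and treatment on the x axis. ONX day 4 pool 1 stands at 12.0 for the oocyte list, and the other 11 arrays lie between 5.00 and 5.84.

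At day 4 after the crush, 19 of 28 genes of the cell cycle list rose, and 14 of 16 rod, 15 of 17 cone, 14 of 19 interneuron and 15 of 20 synapse genes fell. Of the axon regeneration, microglia and matrix lists smaller parts rose, 6 of 42, 5 of 20 and 4 of 36. The part called depends on the spread within all 6 groups as well as on the size of the change. By its median, given below, the microglia list rose more than the cell cycle list. The list tests given below were all lost with an estimated correlation (adjusted p of 0.770 or more). Of the 9301 probe sets, 1582 changed in limma's test, 492 of them higher and 1090 lower in ONX eyes. The gene with the steepest rise was mmp9, a matrix metalloprotease, at 4.64 ± 0.89 (24.9-fold, adjusted p = 0.0176), followed by ccnb1, cyclin B1, at 4.60 ± 1.21 (24.2-fold, adjusted p = 0.0310). The oocyte list also holds ccnb1, which read 13.8 in ONX pool 1 and 8.59 in pool 2, against 6.575 and 6.58 in the SHAM pools. The deepest falls were those of calb2b, which encodes a calretinin, at -2.33 ± 0.34 (5.04-fold lower, adjusted p = 0.0176), and myoz1b, a muscle Z-disc gene, at -2.27 ± 0.46 (adjusted p = 0.0176). In all 492 higher and all 1090 lower probe sets, both ONX pools lay outside both SHAM pools. Across all tested probe sets this held for 24.1% on the higher side and 36.1% on the lower side, where chance gives 16.7% on each. The calls rest on the difference in these same arrays. The agreement among called probe sets, and the medians that follow, are thus not independent evidence. The median difference of the called probe sets from the SHAM mean was 1.29 in ONX pool 1 and 1.00 in pool 2 for those higher, and -1.35 and -0.90 for those lower. With all arrays scaled to the 9 hybridisation controls instead, 2324 passed, 1919 of them higher and 405 lower, and with the 24 poly-A controls 0 passed (smallest adjusted p 0.0624), so that the balance of rises and falls depends on the scaling. The 9 leave out the r2 probe sets of the hybridisation controls, and the fit was not repeated with those. With limma, 0 probe sets passed without ONX pool 1 (2628 at an unadjusted p under 0.05), SHAM pool 1 (2034) or SHAM pool 2 (2300), or with array weights (2148). The count was 4008 without ONX pool 2, 998 and 996 without SHAM day 21 pools 1 and 2, 917 without either ONX day 21 pool, and 10 in a fit of the day 4 arrays alone. With the pool number within a day as a block, limma called 0 (3180 at an unadjusted p under 0.05). The labels do not say how pools were numbered, while a few probe sets, given in the part on processing, go with the number. In every fit without ONX day 4 pool 2, here and below, the array with high oocyte genes stands alone for ONX at day 4. Such fits are no evidence of a stronger response to the crush. A lone array left in a group is assumed to vary like the other groups, here and in every fit with arrays left out. Without the 4 pool 1 arrays of days 12 and 21, where only the day 4 groups supply the spread (2 residual degrees of freedom), it was 10.

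Among the other genes with the largest rises at day 4, several act in DNA replication or the cell cycle. These were rrm2l (4.06 ± 0.87), cdca7a (3.94 ± 0.94), uhrf1 (3.89 ± 0.77), pclaf (3.33 ± 0.79) and mcm2 (3.03 ± 0.79), with kpna2, a nuclear import receptor, at 4.14 ± 0.82. Each rose more in ONX pool 1, the pool with high oocyte genes, than in pool 2, by 5.29 against 2.83 for rrm2l and 3.92 against 2.15 for mcm2. The cathepsin gene ctss2.1 (4.08 ± 0.75) rose by 5.55 in pool 1 and 2.598 in pool 2, and the fibronectin gene fn1a (3.43 ± 1.00) by 2.79 and 4.07. The other large falls were in slc25a4, a mitochondrial ADP/ATP carrier (-2.13 ± 0.53), oaz2b, an ornithine decarboxylase antizyme (-2.00 ± 0.26), gja9a, a connexin (-1.99 ± 0.43), fsta, a follistatin (-1.94 ± 0.35), and mybphb (-1.91 ± 0.57). The NMDA receptor gene grin1a (-1.86 ± 0.42), the muscle calcium pump gene atp2a1 (-1.86 ± 0.55), the myelin gene mbpa (-1.84 ± 0.47), fabp1a (-1.82 ± 0.35) and aqp9b (-1.82 ± 0.38) fell as well. The adjusted p of these 18 genes lay between 0.0176 and 0.0449.

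Of the 42 measured genes of the axon regeneration list, 6 rose and 2 fell at day 4, and 7 and 2 did so when adjusted over the list alone. The transcription factor genes atf3 (3.94 ± 1.18, adjusted p = 0.0455) and sox11b (3.12 ± 0.85, adjusted p = 0.0342) and the tubulin gene tuba1b (2.09 ± 0.62, adjusted p = 0.0458) rose, as did marcksb (2.80 ± 0.75), tuba5 (1.74 ± 0.40) and socs3b (1.89 ± 0.58). The intermediate filament gene inaa (-1.44 ± 0.23) and the axonal adhesion gene cntn1b (-1.42 ± 0.34) fell. For gap43, the growth-associated protein of regrowing axons, the difference was 4.47 ± 1.50 with an adjusted p of 0.0636, which did not pass, while both ONX pools (12.1 and 12.2) lay above both SHAM pools (7.65 and 7.73). The errors of the fit pool the spread within all 6 groups. In gap43 the pools of one label differed far more at day 12, as given below, than at day 4. Values that did not pass either were 1.63 ± 0.64 for jun (adjusted p = 0.0969), 1.02 ± 0.40 for klf6a (0.0997), 1.17 ± 0.53 for sox11a (0.139), 1.16 ± 0.65 for socs3a (0.221), 0.61 ± 0.38 for stat3 (0.268) and -0.02 ± 0.41 for klf7b (0.971). As a list, these genes shifted upwards (median 0.70, 0.41 in pool 1 and 1.02 in pool 2, camera adjusted p = 0.0344; adjusted p = 0.916 with an estimated correlation). The call was lost without SHAM day 4 pool 1 (median 0.58), without ONX day 4 pool 2 (median 0.41) and with arrays scaled to the hybridisation controls (median 1.16, camera adjusted p = 0.457). It also ended without a filter, with array weights and with the pool number as a block (camera adjusted p = 0.0556).

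**Figure D2:**
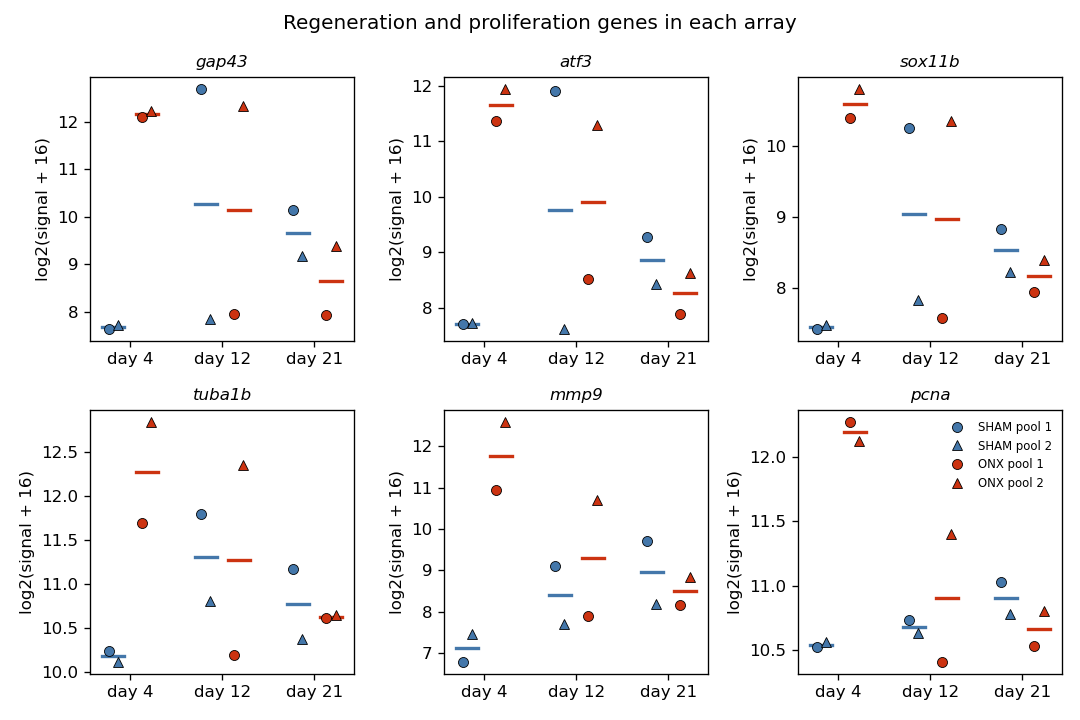
Log2(signal + 16) of gap43, atf3, sox11b, tuba1b, mmp9 and pcna on each of the 12 arrays, by day and treatment (blue SHAM, red ONX; circles pool 1, triangles pool 2; bars are the mean of 2 pools). At day 4 both ONX pools lie above both SHAM pools for each gene, and at day 12 gap43 reads 12.7 in SHAM pool 1 and 7.95 in ONX pool 1.

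The cell cycle list held 28 measured genes at day 4, of which 19 rose and 0 fell, and 22 rose when adjusted over the list alone. They include pcna, the sliding clamp of DNA polymerase (1.66 ± 0.28, adjusted p = 0.0176), the replicative helicase genes mcm5 (2.85 ± 0.58) and mcm7 (1.38 ± 0.41), and the proliferation marker gene mki67 (2.11 ± 0.59). The median of the list was 1.41, and 1.86 in ONX pool 1 against 1.04 in pool 2 (camera adjusted p = 7.5e-10; adjusted p = 0.770 with an estimated correlation). The pool with the larger shift was the one with high oocyte genes, and ccnb1, which is also on the oocyte list, was up by 7.18 there and by 2.01 in pool 2. Of 27 retinal progenitor genes, the chromatin gene hmga1a rose (0.86 ± 0.25) and 8 fell, among them the eye field transcription factor genes pax6a (-1.10 ± 0.25), rx1 (-1.20 ± 0.23) and six3a (-1.07 ± 0.23). When adjusted over the list alone, 1 rose and 9 fell. The progenitor list shifted downwards (median -0.38, camera adjusted p = 0.0125; adjusted p = 0.916 with an estimated correlation), with a median of -0.85 in pool 1 and 0.04 in pool 2. Without ONX pool 1 its adjusted p was 0.494, and with arrays scaled to the hybridisation or poly-A controls its median was 0.080 or 0.011, still lower than the other genes (adjusted p = 0.00226 and 0.0136).

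Photoreceptor genes fell together at day 4. Of 16 rod genes 14 fell, all 16 when adjusted over the list alone, including the rod transducin gene gnat1 (-1.16 ± 0.23), the rod phosphodiesterase gene pde6a (-1.67 ± 0.32) and the outer segment disc gene prph2a (-1.66 ± 0.35). Of 17 cone genes 15 fell, 16 when adjusted over the list alone, among them the cone transducin gene gnat2 (-1.46 ± 0.23) and the cone opsin genes opn1sw1 (-1.08 ± 0.23), opn1sw2 (-1.10 ± 0.24) and opn1lw1 (-0.76 ± 0.20). The rod list had a median of -1.31, with -1.56 in ONX pool 1 and -1.09 in pool 2 (camera adjusted p = 6.3e-09; adjusted p = 0.770 with an estimated correlation). The cone list had a median of -1.004, with -1.22 and -0.78 (camera adjusted p = 2.03e-08; adjusted p = 0.794 with an estimated correlation). Among the 19 interneuron genes 14 fell, 16 when adjusted over the list alone, such as gad2, which makes GABA (-1.57 ± 0.34), and the calretinin gene calb2a (-1.61 ± 0.19). Their median was -1.29, with -1.57 in pool 1 and -0.997 in pool 2 (camera adjusted p = 3.16e-09; adjusted p = 0.770 with an estimated correlation). Of 20 synapse genes 15 fell, also when adjusted over the list alone, including the vesicle genes sv2bb (-1.53 ± 0.22) and sypb (-1.36 ± 0.20) and the SNARE gene snap25a (-1.24 ± 0.24). The synapse list had a median of -1.14, with -1.30 in pool 1 and -0.98 in pool 2 (camera adjusted p = 5.74e-08; adjusted p = 0.770 with an estimated correlation). In each of these 4 lists the larger fall was in the pool with high oocyte genes. Of the spiked controls, those for hybridisation were low in both ONX pools and the poly-A controls in pool 1 only. The hybridisation controls lay at -0.51 in ONX pool 1 and -0.40 in pool 2 against the SHAM mean of day 4 (-0.28 to 0.024 on the other 8 arrays), and the poly-A controls at -0.90 and 0.15 (-0.40 to 0.15 elsewhere). The r2 probe sets of the hybridisation controls, left out of the scaling, also lay below both SHAM day 4 arrays in both ONX pools. The size of the falls thus depends on the scaling of the arrays. Scaled to the hybridisation controls, the rod, cone, interneuron and synapse medians were -0.85, -0.55, -0.83 and -0.68, and scaled to the poly-A controls -0.92, -0.62, -0.90 and -0.75, and all 8 passed in camera. The scaling was chosen after the values were seen, and the labels do not say how the controls were added.

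Retinal ganglion cells are the neurons whose axons the crush injures. Of their 11 measured genes 5 fell at day 4, 6 when adjusted over the list alone while 1 rose. Those that fell over all tested probe sets were isl1a (-1.22 ± 0.20), irx4a (-1.82 ± 0.26), robo2 (-1.16 ± 0.23), sncgb (-1.47 ± 0.27), which is also on the synapse list, and chrnb3a (-1.04 ± 0.19). The list median was -0.63, with -0.81 in ONX pool 1 and -0.45 in pool 2 (camera adjusted p = 0.0458; adjusted p = 0.816 with an estimated correlation). Scaled to the hybridisation controls the median was -0.17, and the call held. This call was lost without either ONX day 4 pool (adjusted p = 0.0572 and 0.0948), without SHAM day 12 pool 1 (0.0550) or pool 2 (0.0660), without ONX day 12 pool 1 (0.0630) or pool 2 (0.0723), and without SHAM day 21 pool 1 (0.0545). Of 16 Mueller glia genes, glulb rose (0.99 ± 0.21) and 5 fell, among them the glutamine synthetase gene glula (-0.82 ± 0.24) and the retinoid-binding gene rlbp1a (-0.91 ± 0.26). Adjusted over the list alone, 1 rose and 8 fell. The intermediate filament gene gfap had a difference of 0.26 ± 0.44 (adjusted p = 0.689). The Mueller glia list had a median of -0.49 (camera adjusted p = 0.129), with -0.59 in pool 1 and -0.08 in pool 2, and passed without ONX pool 2 (adjusted p = 0.0361).

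Of 20 microglia and macrophage genes 5 rose at day 4 and 0 fell, and 10 rose when adjusted over the list alone. The lysosomal cathepsin genes ctss2.1 (4.08 ± 0.75), ctsc (1.90 ± 0.55) and ctsba (1.76 ± 0.34) rose, with the complement gene c1qc (1.65 ± 0.47) and the NADPH oxidase gene cyba (1.096 ± 0.31). Unlike the list as a whole, ctss2.1 rose more in ONX pool 1, the pool with high oocyte genes, than in pool 2, as given above. The list median was 1.49, with 0.79 in ONX pool 1 and 2.06 in pool 2 (camera adjusted p = 5.96e-05; adjusted p = 0.866 with an estimated correlation). Of 36 extracellular matrix genes 4 rose and 2 fell, also when adjusted over the list alone. Those that rose were mmp9, fn1a, the prolyl hydroxylase gene p4ha1b (1.41 ± 0.32) and the collagen gene col12a1b (1.00 ± 0.20), while lama5 (-1.02 ± 0.31) and tnr (-1.34 ± 0.28) fell. Their median was 0.99, with 0.45 in pool 1 and 1.42 in pool 2 (camera adjusted p = 0.00172, and 0.916 with an estimated correlation). The call was lost without ONX pool 2 (median 0.45). It was also lost with arrays scaled to the hybridisation controls (camera adjusted p = 0.158), at a larger median of 1.45. That scaling raises the day 4 difference of every gene alike, and why the call ended was not tested. Among 54 cell stress genes 9 rose and 2 fell, 10 and 2 when adjusted over the list alone. The chaperone genes hspa5 (1.93 ± 0.44) and hsp90b1 (1.77 ± 0.48) of the endoplasmic reticulum and the peroxiredoxin gene prdx1 (1.96 ± 0.34) rose, and the superoxide dismutase gene sod2 (-0.66 ± 0.18) fell. The stress list had a median of 0.33, with 0.06 in pool 1 and 0.41 in pool 2 (camera adjusted p = 0.0242; adjusted p = 0.770 with an estimated correlation), and lost its call without ONX pool 2 (adjusted p = 0.161) or with arrays scaled to the hybridisation controls (0.0563, median 0.78).

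A further 4 lists shifted downwards at day 4. Of 11 lens genes 4 fell, 10 when adjusted over the list alone, among them the crystallin genes crybb1 (-1.01 ± 0.25) and cryba4 (-1.07 ± 0.29). The lens list had a median of -0.94, with -1.03 in ONX pool 1 and -0.46 in pool 2 (camera adjusted p = 0.000187; adjusted p = 0.816 with an estimated correlation). Of 12 erythrocyte genes 4 fell, 9 when adjusted over the list alone, among them the red cell transcription factor gene klf1 (-1.26 ± 0.27) and the spectrin gene sptb (-1.14 ± 0.29). Their median was -1.11, with -1.17 and -0.90 in the pools (camera adjusted p = 0.000483; adjusted p = 0.811 with an estimated correlation). Of 22 circadian clock genes 9 fell, 11 when adjusted over the list alone, including per2 (-0.99 ± 0.25), cry1a (-1.13 ± 0.27) and aanat2, which acts in melatonin synthesis (-1.41 ± 0.31). The clock list had a median of -0.78, with -0.96 and -0.75 in the pools (camera adjusted p = 3.45e-05; adjusted p = 0.811 with an estimated correlation). Of 83 respiratory chain genes 7 fell, 5 when adjusted over the list alone, among them ndufs1 (-1.04 ± 0.22) and uqcrb (-0.88 ± 0.23). Their median was -0.40, with -0.48 and -0.28 in the pools (camera adjusted p = 8.75e-07, and 0.916 with an estimated correlation). With arrays scaled to the hybridisation controls it was 0.062, and the call of a shift below the other genes held.

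The other 12 lists, Mueller glia among them, did not pass at day 4. Single genes changed in several of them, such as hp (2.21 ± 0.68) and c1qc in the complement list (2 of 10 rose, 3 when adjusted over the list alone; median 0.71, 0.10 in pool 1 and 1.35 in pool 2, adjusted p = 0.216) and isg15 (2.17 ± 0.63) in the antigen presentation and interferon list (1 of 17 rose, 0 when adjusted over the list alone; median 0.36, 0.05 and 0.81 in the pools, adjusted p = 0.136). In the neutrophil list, mmp9 alone of 8 rose, also when adjusted over the list alone (median 0.92, 0.38 and 1.64 in the pools, adjusted p = 0.0749). The neutrophil list passed without ONX pool 1 (1.64, adjusted p = 0.00357), SHAM pool 2 (0.0170) or ONX day 21 pool 2 (0.0465). The complement, interferon and ribosomal protein lists passed without ONX pool 1 (medians 1.35, 0.81 and 0.38, adjusted p = 0.0181, 0.0102 and 1.14e-07). Of 33 skeletal muscle genes 4 fell, 2 when adjusted over the list alone, including atp2a1 and pgam2 (-1.48 ± 0.37), at a list median of 0.01 (-0.63 and 0.66 in the pools) and a mean of 0.05 with a downward test (adjusted p = 0.650). Of 28 surface epithelium genes krt18a.1 rose (1.70 ± 0.45) and krt97 fell (-0.85 ± 0.23), with 0 when adjusted over the list alone (median 0.00, -0.21 and 0.18 in the pools, mean 0.12, test downward with adjusted p = 0.988). Of 9 pigment genes rab32a (1.04 ± 0.21) and pcbd1 (0.93 ± 0.25) rose and otx2b (-1.02 ± 0.26) fell, with 3 and 4 when adjusted over the list alone (median -0.43, -1.06 and 0.08 in the pools, adjusted p = 0.751). Of 17 lipid genes npc2.1 (1.69 ± 0.29) rose and 3 fell, also when adjusted over the list alone (median -0.06, -0.11 and -0.05 in the pools, mean 0.06, test downward with adjusted p = 0.487). Of 7 myelin genes mbpa fell, also when adjusted over the list alone (median 0.11, 0.03 and 0.19 in the pools, mean -0.19, test downward with adjusted p = 0.822). Of 79 ribosomal protein genes rpl7l1 rose (1.37 ± 0.27), also when adjusted over the list alone (median 0.08, -0.22 and 0.38 in the pools, adjusted p = 0.280). In the 10 inflammatory cytokine genes (median 0.17, -0.10 and 0.47 in the pools, adjusted p = 0.551) and the 23 immediate early genes (median -0.07, -0.22 and 0.67 in the pools, mean 0.04, test downward with adjusted p = 0.988), 0 passed in limma's test, also when adjusted over the list alone, the closest being nfkb2 (0.73 ± 0.23, adjusted p = 0.0560) and dusp1 (1.13 ± 0.35, adjusted p = 0.0530).

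**Figure D3:**
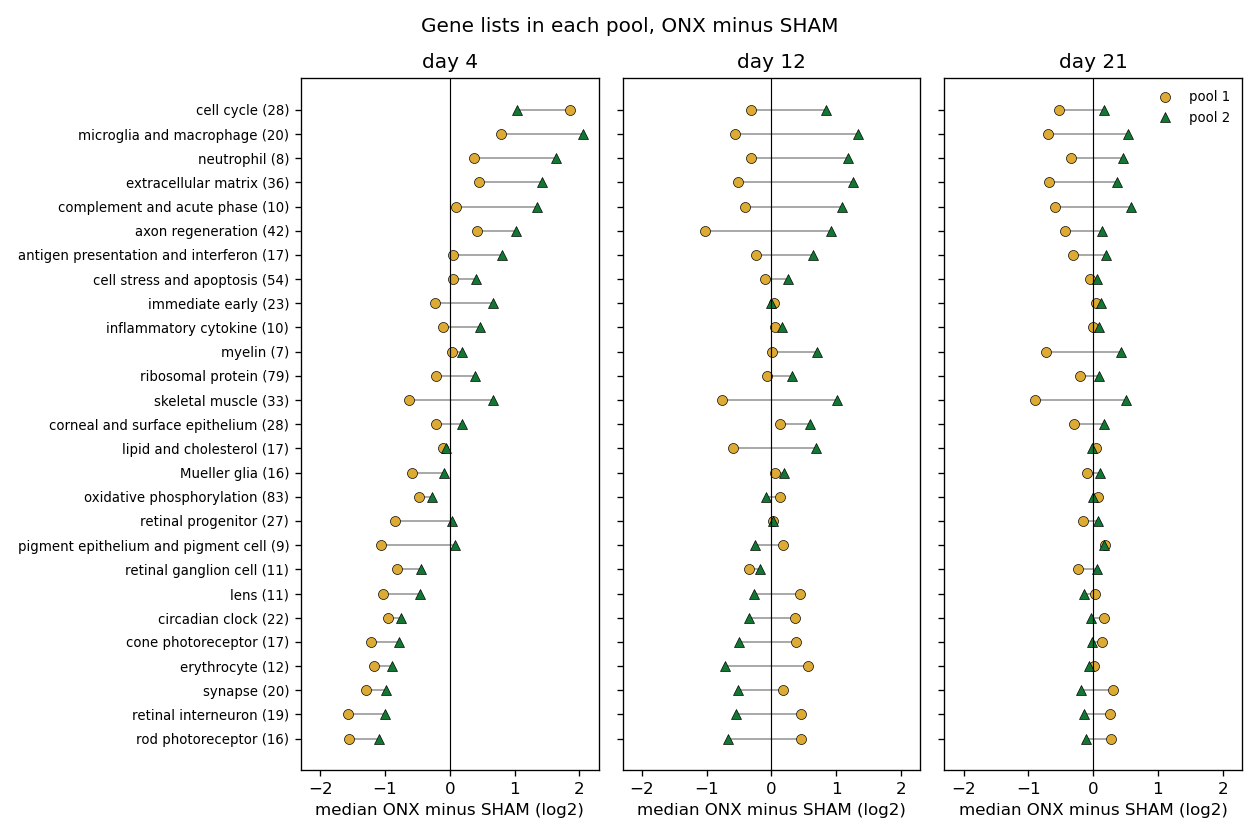
Median log2 difference of the 27 gene lists in each pool, ONX minus SHAM, against the mean of both SHAM pools at day 4 and against the same-numbered SHAM pool at days 12 and 21 (circles pool 1, triangles pool 2; 1 point per list and pool). For the rod list both day 4 pools lie below 0 (-1.56 and -1.09), while day 12 reads 0.45 in pool 1 and -0.68 in pool 2.

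At day 12 gap43, sox11b and atf3 differed between pools of one label more than between labels. In gap43 the log2 signal was 12.7 and 7.85 in the libraries labelled SHAM pools 1 and 2, and 7.95 and 12.3 in those labelled ONX pools 1 and 2, a difference of -0.13 ± 1.50 (adjusted p = 1.00). The same holds for sox11b (10.2 and 7.83 in SHAM, 7.59 and 10.3 in ONX; difference -0.07 ± 0.85) and atf3 (11.9 and 7.63, 8.51 and 11.3; difference 0.13 ± 1.18). With limma, 0 of 9301 probe sets passed, 27 had an unadjusted p under 0.05, and the smallest adjusted p was 1.00. Among the genes with the smallest p were the myelin gene mbpa (1.72 ± 0.47), stxbp6l (1.38 ± 0.40), the keratin gene krt15 (0.60 ± 0.21), the tetraspanin gene cd9b (0.98 ± 0.36) and mrpl32 (0.71 ± 0.26). For mbpa, stxbp6l and krt15 the SHAM means, given below, were lower at day 12 than at days 4 and 21. On the lower side were phrf1 (-0.51 ± 0.18), sona (-0.58 ± 0.21), ublcp1 (-0.56 ± 0.21), hcfc1b (-0.53 ± 0.23) and the aquaporin gene aqp8a.1 (-0.52 ± 0.23). The axon regeneration list had a median of -0.06 (camera adjusted p = 0.440), with -1.02 in pool 1 and 0.93 in pool 2. The list passed upwards without SHAM pool 1 (0.42, adjusted p = 3.29e-06) or ONX pool 1 (0.50, adjusted p = 0.000733), and downwards without SHAM pool 2 (-0.51, adjusted p = 6.41e-12) or ONX pool 2 (-0.44, adjusted p = 1.24e-08). Without both pool 1 libraries of day 12 the count of probe sets stayed at 0 (601 at an unadjusted p under 0.05). Without the 4 pool 1 libraries of days 12 and 21 it was 0 (300). Both fits compare a single ONX with a single SHAM array at day 12, and other groups supply the spread (4 and 2 residual degrees of freedom).

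Of the 27 lists 8 shifted upwards and 5 downwards at day 12, while no single member passed over all tested probe sets. When adjusted over the list alone, 1 myelin gene rose and 0 other list members passed in limma's test. The surface epithelium list had the smallest p, with 27 of 28 genes above 0 (median 0.33, 0.14 in pool 1 and 0.60 in pool 2, camera adjusted p = 3.35e-14; adjusted p = 0.770 with an estimated correlation). Of the 79 ribosomal protein genes 78 were above 0 (median 0.13, -0.07 in pool 1 and 0.32 in pool 2, camera adjusted p = 1.1e-07), and so were 27 of 28 cell cycle genes (median 0.28, -0.31 and 0.84, camera adjusted p = 1.6e-06) and 31 of 36 matrix genes (median 0.33, -0.51 and 1.26, camera adjusted p = 7.43e-05). With an estimated correlation these had adjusted p of 0.916, 0.811 and 0.916. The myelin (median 0.27, adjusted p = 0.000171), microglia (0.32, adjusted p = 0.000915), complement (0.34, adjusted p = 0.00303) and interferon lists (0.20, adjusted p = 0.0130) shifted upwards as well, with adjusted p = 0.770, 0.916, 0.831 and 0.916 with an estimated correlation. In the myelin list SHAM day 12 pool 2 was the lowest of the 12 arrays, at -0.55 against the mean of all arrays. The synapse (median -0.12, adjusted p = 0.00111), rod (-0.14, adjusted p = 0.00748), erythrocyte (-0.17, adjusted p = 0.0201), ganglion cell (-0.16, adjusted p = 0.0374) and interneuron lists (-0.12, adjusted p = 0.0374) shifted downwards. Their adjusted p was 0.866, 0.916, 0.916, 0.811 and 0.916 with an estimated correlation, in that order.

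These shifts at day 12 rested on single libraries. Of the 13 calls, 10 ended (adjusted p between 0.0629 and 0.975) and that of the erythrocyte list turned upwards (0.28, adjusted p = 0.00539) without SHAM day 12 pool 2. Without ONX day 12 pool 2, 8 ended (adjusted p between 0.0531 and 0.985). The rod list then turned upwards (0.24, adjusted p = 0.00963) and the microglia (-0.31, adjusted p = 0.00748), interferon (-0.23, adjusted p = 0.0126) and matrix lists (-0.46, adjusted p = 6.51e-06) turned downwards. The ganglion cell call also ended without SHAM pool 1 (adjusted p = 0.916) or ONX pool 1 (0.591) of that day, and with ONX day 4 pool 1 (0.0611) or pool 2 (0.0758) left out, and the interneuron call without ONX day 4 pool 2 (0.0502). The surface epithelium call held without each of the 12 arrays. It goes with low SHAM values: set against the mean of all arrays, SHAM day 12 pools 1 and 2 lay lowest of the 12 at -0.43 and -0.56, below the 0.029 to 0.30 of the other SHAM arrays, while the 2 ONX day 12 arrays lay at -0.24 and -0.041. Some lists without a call passed on leaving out 1 array: axon regeneration, cone and lipid in 4 cases each (2 upwards and 2 downwards), lens and respiratory chain in 3, clock and muscle in 2, and stress, neutrophil and pigment in 1. In pool 1 the rod (0.45), cone (0.38) and interneuron (0.46) lists lay above 0, and in pool 2 they lay at -0.68, -0.51 and -0.54.

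At day 21 no difference in a single gene passed. In limma's test 0 of 9301 probe sets passed, 12 had an unadjusted p under 0.05, and the smallest adjusted p was 1. The genes with the smallest p were mark2a (0.67 ± 0.20), zfand3 (0.72 ± 0.23), pdcd2l (1.07 ± 0.41), emsy (0.46 ± 0.19) and zfpl1 (0.54 ± 0.22) on the higher side. On the lower side they were sh3d21 (-0.58 ± 0.24), the Wnt receptor gene fzd9b (-0.81 ± 0.34), fcho2 (-0.50 ± 0.23), wdr77 (-0.40 ± 0.18) and lhfpl2a (-0.60 ± 0.27). For gap43 the difference was -1.01 ± 1.50, with 10.2 and 9.18 in the libraries labelled SHAM pools 1 and 2 and 7.93 and 9.38 in those labelled ONX. The differences of atf3 (-0.59 ± 1.18), sox11b (-0.37 ± 0.85), tuba1b (-0.14 ± 0.62) and pcna (-0.24 ± 0.28) did not pass either. Without the 4 pool 1 libraries of days 12 and 21 the count was 0 (20 at an unadjusted p under 0.05), from 1 ONX and 1 SHAM array at that day.

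One list, that of cone genes, shifted upwards at day 21 (14 of 17 above 0, median 0.08, camera adjusted p = 0.0357; adjusted p = 0.916 with an estimated correlation). The ribosomal protein (median -0.06, adjusted p = 0.0109), cell cycle (-0.15, adjusted p = 0.0282), skeletal muscle (-0.21, adjusted p = 0.0292) and matrix lists (-0.20, adjusted p = 0.0380) shifted downwards. Their adjusted p was 0.941, 0.916, 0.916 and 0.916 with an estimated correlation. In all 5 lists the pools lay on opposite sides of 0. The medians in pools 1 and 2 were 0.14 and -0.02 for cone and -0.21 and 0.085 for ribosomal protein. They were -0.52 and 0.16 for cell cycle, -0.90 and 0.52 for muscle, and -0.68 and 0.37 for matrix. With limma, 0 members of any of the 27 lists passed, also when adjusted over the list alone. All 5 calls ended without SHAM day 21 pool 1 (adjusted p between 0.271 and 0.872). Without ONX day 21 pool 1, 4 ended (adjusted p between 0.0852 and 0.644) and that of the muscle list turned upwards (0.33, adjusted p = 0.000239). The cone, muscle and matrix calls also ended without ONX day 4 pool 1 (adjusted p = 0.0525, 0.0780 and 0.0641) or pool 2 (0.0643, 0.0948 and 0.0788). The axon regeneration list had a median of -0.10 (camera adjusted p = 0.0670), with -0.43 in pool 1 and 0.13 in pool 2. It passed downwards without SHAM day 21 pool 2 (-0.23, adjusted p = 0.00276), without ONX day 21 pool 2 (-0.29, adjusted p = 0.00239), and without each of the 4 day 12 arrays, at adjusted p of 0.0177 and 0.0215 for SHAM pools 1 and 2 and 0.0165 and 0.0184 for ONX pools 1 and 2. The immediate early list (median 0.07, adjusted p = 0.0670) passed upwards without ONX day 21 pool 1 (0.20, adjusted p = 1.2e-06) or SHAM day 21 pool 2 (0.36, adjusted p = 1.26e-06). Other lists without a call also passed on leaving out 1 array: respiratory chain in 4 cases, interferon, complement, surface epithelium, microglia, myelin, neutrophil, rod and synapse in 2, and Mueller glia and interneuron in 1.

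On the average of the 3 days, no gene passed. Among those with the smallest p on the higher side, the nucleolar gene npm1a had a difference of 0.69 ± 0.15, the growth factor gene hbegfa 0.74 ± 0.16, wdr3 0.54 ± 0.13, rab20 0.52 ± 0.12 and col12a1b 0.50 ± 0.12. On the lower side were calb2a (-0.67 ± 0.11), neff1 (-0.79 ± 0.15), the complexin gene cplx2a (-0.66 ± 0.13), oaz2b (-0.78 ± 0.15) and the mitochondrial creatine kinase gene ckmt2a (-0.53 ± 0.11). The adjusted p was 0.284 for each of these, and for ckmt2a the differences at days 12 and 21 were 0.01 and 0.02. In limma's test 0 of 9301 probe sets passed and 1390 had an unadjusted p under 0.05. The count was 1374 without ONX day 4 pool 2, 7 without both day 12 pool 1 libraries, and 4 without the 4 pool 1 libraries of days 12 and 21, where days 12 and 21 hold 1 array per group.

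On average 4 lists shifted upwards and 10 downwards, the cell cycle (median 0.51, camera adjusted p = 1.49e-10), microglia (0.60, adjusted p = 1.42e-05), matrix (0.40, adjusted p = 0.00111) and cell stress lists (0.08, adjusted p = 0.0222) being higher. Their adjusted p was 0.770, 0.847, 0.916 and 0.770 with an estimated correlation. The lower ones were the interneuron (-0.42, adjusted p = 3.58e-09), rod (-0.47, adjusted p = 5.26e-09), synapse (-0.42, adjusted p = 9.42e-09) and cone lists (-0.35, adjusted p = 1.1e-07), with adjusted p of 0.770, 0.770, 0.770 and 0.803 with an estimated correlation. The clock (-0.30, adjusted p = 0.000192), erythrocyte (-0.42, adjusted p = 0.000206), respiratory chain (-0.11, adjusted p = 0.000210), lens (-0.26, adjusted p = 0.00114), ganglion cell (-0.33, adjusted p = 0.00821) and progenitor lists (-0.22, adjusted p = 0.0125) followed, with adjusted p of 0.831, 0.803, 0.916, 0.866, 0.770 and 0.916 with an estimated correlation. The average includes day 4, where each of these lists was called in the same direction at a larger median. At day 21 the cell cycle and matrix lists were called downwards and the cone list upwards (0.076, against -1.004 at day 4). The calls on average are therefore not shown to be shared by the 3 days. When adjusted over the list alone, 15 rod, 15 synapse, 7 cone, 5 ganglion cell and 3 interneuron genes fell and 6 cell cycle genes rose, as did 1 matrix and 1 pigment gene, while 1 lipid gene rose and 1 fell. Of these calls, the progenitor list ended without ONX day 4 pool 1 (adjusted p = 0.346), SHAM day 12 pool 1 (0.109) or SHAM day 21 pool 1 (0.0576), and the ganglion cell list without SHAM (0.0698) or ONX (0.0661) day 12 pool 1. The matrix list ended without ONX day 4 pool 2 (0.405) or ONX day 12 pool 2 (0.223), the stress list without ONX day 4 pool 2 (0.136), and the respiratory chain list without SHAM day 12 pool 2 (0.0842). The neutrophil list (0.34, adjusted p = 0.0509) passed without any 1 of 6 arrays (adjusted p between 0.00288 and 0.0428; 0.61 without ONX day 4 pool 1), and the complement list (0.31, adjusted p = 0.0644) without any 1 of 5 (between 0.00522 and 0.0431; 0.52 without ONX day 4 pool 1). Other lists without a call passed too: interferon in 5 cases, ribosomal protein in 3, muscle (downwards) in 3, axon regeneration and surface epithelium in 2, and Mueller glia and lipid (downwards) in 1.

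Whether the effect of the crush differed between the 3 days was tested for each probe set. The genes with the smallest p were ckmt2a, the creatine kinase gene named above (-1.62, 0.01 and 0.02 at days 4, 12 and 21), gatd3l (-1.46, -0.01 and 0.07), usp21, a deubiquitinase (-1.72, 0.04 and -0.09), and the glycogen phosphorylase gene pygl (1.47, -0.02 and -0.25). For calb2a the values were -1.61, -0.24 and -0.17, for sv2bb -1.53, -0.11 and 0.08, for grtp1a -1.42, -0.08 and 0.13, and for npm1a 1.90, 0.13 and 0.04. The standard error of these differences was between 0.19 and 0.26. In limma's F-test 0 of 9301 probe sets passed, 1308 had an unadjusted p under 0.05, and the smallest adjusted p was 0.261. A change called at day 4 is therefore not shown to differ from that at day 12 or 21. The count was 1419 without ONX day 4 pool 2, 0 without both day 12 pool 1 libraries (1378 at an unadjusted p under 0.05), and 0 without the 4 pool 1 libraries of days 12 and 21 (159).

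Between SHAM eyes of different days, no gene passed. Among those with the smallest p, the protease gene capn9 had a mean log2 signal of 9.31, 7.86 and 9.38 at days 4, 12 and 21, and the keratin gene krt15 of 13.8, 12.1 and 13.3 (adjusted p = 0.0830 each). The means of zgc:193505 were 10.2, 9.53 and 11.2 (adjusted p = 0.0830), those of mbpa 12.7, 10.4 and 12.9, of stxbp6l 10.1, 8.00 and 10.1, and of cops4 6.96, 8.36 and 9.13 (adjusted p = 0.414 each). In limma's F-test 0 of 9301 probe sets passed and 172 had an unadjusted p under 0.05. With array weights 7 passed, and with arrays centred on their median 3.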

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

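The tests of explanations in this part were chosen after the results were seen, apart from the splits of the arrays within days, which were planned beforehand.

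ONX day 4 pool 1 stands apart by its oocyte genes. Among 13 oocyte genes not looked at before the list was written, the median lay 4.09 log2 above the highest other array and 11 lay over 2 above it, while 21 testis genes lay at -0.52 and 9 germ cell genes at 2.90, which is consistent with oocyte RNA in that pool. The labels give male fish, and how such RNA came into the sample is not known from the data. Degraded RNA is argued against, as the 3' minus 5' difference of GAPDH was 0.817 on that array and 0.518 to 1.06 on the others (acta1 2.32, others 0.842 to 2.70). Oocyte RNA could lower the share of other transcripts, but as the whole cause of the lower rod, cone, interneuron and synapse lists it is argued against: in ONX pool 2, without those genes, the 72 members had a median of -0.94 and 68 lay below both SHAM arrays, whose own difference was 0.0785 (pool 1 -1.32). The controls of that pool go both ways (hybridisation -0.40, poly-A 0.15), so the -0.94 could be smaller or larger with another scaling.

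At days 12 and 21 the ONX minus SHAM differences of pool 1 ran against the day 4 response. Over the 1582 probe sets called at day 4, the ONX minus SHAM difference of day 12 correlated with that of day 4 at -0.678 in pool 1 and 0.870 in pool 2, and the pools with each other at -0.733; at day 21 it was -0.716 in pool 1 and 0.510 in pool 2. The day 4 sign was shared by 17.7% and 95.2% at day 12 and by 14.0% and 72.0% at day 21, which is consistent with crushed and sham eyes exchanged in pool 1 at day 12, by a swap of tubes or a crush on the other side. At day 21 the same reading is weaker and stays open, since in pool 2 the axon regeneration list differed by 0.13 and gap43 read 9.18 in SHAM and 9.38 in ONX. The differences take libraries by number; with numbers crossed at day 12, the axon regeneration list differed by -0.022 and -0.16, as each label holds 1 high and 1 low library. A response to the sham operation on top of that to the crush, or one to the crush over by day 12 or 21, stays open: from the highest of the day 4 SHAM arrays and SHAM day 12 pool 2, that list lay at -0.022 in ONX day 12 pool 1, 0.889 in ONX pool 2 and 1.05 in SHAM pool 1, each a single library, and day 21 rests on the 0.510 of pool 2.

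For the lists on the average over the 3 days, the splits of the arrays within days cannot exclude chance. Adjusted within each split, the real labels called 15 lists. Of the 100 splits 31 called as many, the real one among them, and the highest other called 20. Several of these splits keep the day 4 labels, and with them the day 4 difference. The 31 therefore do not give how often chance alone calls as many. For genes the splits decide nothing, since the real labels called 0 (limma; 1390 at an unadjusted p under 0.05) and all 100 splits call at least that. The highest other split called 1997 genes and exchanges the labels of the pool 1 libraries of days 12 and 21, and the one that exchanges day 12 pool 1 alone called 893. That split restates the structure of the samples given above and adds no evidence.

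In ONX day 4 pool 1, 287 of the 6201 probe sets below the signal limit lay over 3 log2 above every other array, and 0 did so on each other array, as counts without a test. The cone list had a median of -1.004 at day 4 and 0.076 at day 21, and the Mueller glia list -0.49 at day 4 and 0.082 at day 12; the difference between days was not tested for lists.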

How the results depend on the processing

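All settings were planned before the values were seen except those without several pool 1 arrays, the crossed block and the scaling to controls; unless stated otherwise the cause was not tested.

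The day 4 count of 1582 was 2813 at an adjusted p under 0.10, 10 with the arrays of that day alone, and in limma 0 with array weights (2148 at an unadjusted p under 0.05). It was 2324 with arrays scaled to hybridisation controls (1919 higher, 405 lower) and 0 with poly-A controls (2146). Leaving out 1 array gave 0 to 4008: 0 without ONX day 4 pool 1 (2628), SHAM day 4 pool 1 (2034) or SHAM day 4 pool 2 (2300), 4008 without ONX day 4 pool 2, 998 and 996 without SHAM day 21 pools 1 and 2, and 917 without ONX day 21 pool 1 or pool 2. Without the 4 pool 1 arrays of days 12 and 21 it was 10, and without these and ONX day 4 pool 1 it was 3379. In that last fit, called the fit without the 5 below, every group but SHAM day 4 holds 1 array, and the spread of this one pair (1 residual degree of freedom) stands for all, so that its counts are no evidence of more changes. Of 177 called gene results at day 4, 0 were kept with array weights or without any 1 of the 3 arrays that ended the count, 121 with hybridisation and 0 with poly-A controls, and none changed sign.

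At day 12 the count was 2 at an unadjusted p under 0.01 with a 2-fold change and 1114 without the 5 pool 1 arrays named; at day 21 it was 10 without those 5. On average it was 4 with the 2-fold rule, 1 without a filter, 7 without both day 12 pool 1 arrays, 4 without the 4 pool 1 arrays, 3078 without the 5, and 0 to 1374 on leaving out 1 array (1374 without ONX day 4 pool 2). For the difference between days it was 569 without the 5, and 0 to 1419 on leaving out 1 array (1419 without ONX day 4 pool 2). Between SHAM days it was 3 at an adjusted p under 0.10, 3 with median centring, 7 with array weights and 171 without the 5.

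Of 108 list tests 47 passed, 0 with an estimated correlation (smallest adjusted p 0.770), 0 with fry (0.0610), 72 without the 5 arrays, and 38 to 59 on leaving out 1. Without any 1 array 10 of 15 day 4, 1 of 13 day 12, 0 of 5 day 21 and 9 of 14 average calls held. At day 4 the axon regeneration, progenitor and stress calls ended without a filter, the ganglion cell and erythrocyte calls with the upper 40%, the ganglion cell call with quantile normalization or the mean of probe sets, and the axon regeneration and ganglion cell calls with array weights. Lists numbered 53 with hybridisation and 59 with poly-A controls. With hybridisation controls the axon regeneration (0.457), matrix (0.158) and stress (0.0563) calls at day 4 ended at larger medians (1.16, 1.45 and 0.78) and Mueller glia (0.0384), muscle (0.0293) and ribosomal protein (0.0286) passed; with poly-A controls neutrophil (0.00842), interferon (0.0342) and ribosomal protein (0.0144) passed, and at day 12 the ganglion cell call ended with either (0.0818 and 0.0507). Newly passing at day 12, day 21 and on average were 3, 2 and 2 lists with hybridisation and 1, 3 and 6 with poly-A controls.

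Leaving out 1 array turned 16 list results, counted where the list passed in the other direction; medians of other lists changed sign without passing, such as cell cycle (0.28 to -0.060), complement (0.34 to -0.075) and interneuron (-0.12 to 0.18) at day 12 and matrix (-0.20 to 0.13) at day 21. The 16 had these ranges at day 12: axon regeneration -0.51 to 0.50, lens -0.15 to 0.20, lipid -0.30 to 0.37, respiratory chain -0.15 to 0.20, cone -0.26 to 0.19, erythrocyte -0.59 to 0.28, rod -0.45 to 0.24, microglia -0.31 to 0.86, interferon -0.23 to 0.54, muscle -0.69 to 0.92, matrix -0.46 to 1.26 and clock -0.40 to 0.35. At day 21 they were microglia -0.47 to 0.28, neutrophil -0.38 to 0.23, muscle -0.74 to 0.33 and complement -0.55 to 0.42. Without the day 12 pool 1 arrays, the 4 or the 5, axon regeneration at day 12 was 0.93, lens -0.26 and lipid 0.70. Without the 4 or the 5, day 21 gave axon regeneration 0.13, interneuron -0.14, microglia 0.53, neutrophil 0.47, interferon 0.20, muscle 0.52, surface epithelium 0.17, myelin 0.44, matrix 0.37, ribosomal protein 0.085 and synapse -0.19. The average of muscle was 0.57 and 0.81. Without the 5 only, rod at day 21 was -0.11, cell cycle 0.16, and muscle at day 4 0.66. Of 786 gene results 9 turned, all at day 12 without the 5, where 1 ONX array is set against 1 SHAM array: ca2 -0.63, gap43 4.47, guca1c -0.77, jun 1.74, klf6a 1.00, marcksb 2.09, opn1mw4 -0.50, sox11b 2.51 and tuba1b 1.54.

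Same-numbered pools of a day share only a number as far as the labels tell, and their deviations from the group means correlated at 0.124, -0.122 and -0.0282 at days 4, 12 and 21. In a few probe sets the libraries of a day formed pairs alike within 1 log2 and 3 log2 apart. An ONX and a SHAM library of the same number paired in 3, 7 and 2 of them at those days, and crossed numbers in 0, 6 and 0. Of the 6 crossed, 5 lay over 2 log2 from SHAM in ONX day 4 pool 2, gap43 among them, and 2 of the 7. These few probe sets go with shared fish in same-numbered pools, but the labels do not settle the meaning of the number. With that number as a block (3 residual degrees of freedom), limma called 0 genes at day 4 (3180 at an unadjusted p under 0.05), day 12 (21), day 21 (7), on average (1137), for the difference between days (985) and, with the numbers as 2 blocks, between SHAM days (172). On simulated data it recovered 3 of 67 probe sets changed 2-fold (4.48%), 52 of 67 changed 4-fold (77.6%) and 60 of 66 changed 8-fold (90.9%), with 4 false among 119 calls. The block gave 48 lists. Those no longer called were axon regeneration (adjusted p = 0.0556) and ganglion cell (0.0727) at day 4 and ganglion cell at day 12 (0.0727), and newly called were neutrophil at day 4 (0.0355), immediate early at day 21 (0.0111), and neutrophil (0.0189) and complement (0.0308) on average; it changed no other call. Numbers crossed at day 12 gave 1677 genes at day 4 and 0 at day 12, day 21, on average and for the difference between days; it was not run for SHAM days or lists.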

Other observations

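The values in this part were picked out after the results were seen, and none was tested beyond the tests given above.

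In several gene groups the ONX pools of day 4 lay on opposite sides of SHAM. Skeletal muscle genes had a median of -0.63 in pool 1 and 0.66 in pool 2, immediate early genes -0.22 and 0.67, ribosomal protein genes -0.22 and 0.38, and surface epithelium genes -0.21 and 0.18. Inflammatory cytokine genes had -0.10 and 0.47, and pigment genes -1.06 and 0.08. Of the probe sets called at day 4, 48 of those higher and 433 of those lower carry no gene symbol.

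At day 12 the pools also differed by group. Microglia genes had a median of -0.56 in pool 1 and 1.33 in pool 2, complement genes -0.41 and 1.09, muscle genes -0.77 and 1.02, and neutrophil genes -0.31 and 1.18. At day 21 microglia genes had -0.69 and 0.53, complement genes -0.59 and 0.59, muscle genes -0.90 and 0.52, myelin genes -0.73 and 0.44, and rod genes 0.27 and -0.11.

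The median of a list, its mean and the direction of its test differed in sign in 13 of the 108 list tests, and 0 of these passed in limma's camera.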
